A study of Columba livia with 10 samples.

How the data were processed

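The cerebellum of 10 racing homers was dissected, kept in RNAlater at -20 °C and extracted as total RNA, with RNA integrity numbers of 9.6 to 10.0, per the labels. Libraries were read as 100 bp pairs on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name fastp 0.23.2, FastQC 0.11.5, MultiQC 1.14, STAR 2.7.10a and HTSeq 0.13.5, without parameters. The genome build and annotation, the strand setting of the counting and the library kit are not given in the sources used here. The deposited values are raw read counts per gene, 1 table per sample, with no normalization by the authors. Each table has rows of its own for reads aligned to more than 1 place, 2.37% to 3.90% of counts, and for reads on overlapping genes, 0.184% to 0.249%, so counts of genes with near-identical copies or overlapping neighbours are uncertain.

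Rows that name no gene, such as reads outside features, held 18.1% to 23.4% of the counts, more in every race library than in 4 of the 5 control libraries, and stayed out of library sizes and tests. Ribosomal RNA genes held 0.187% to 1.06% of the gene counts and a single uncharacterised gene, LOC135578006, held 3.79% to 9.04%. Gene names were used as the tables give them, and 22268 of 22547 matched the RefSeq gene table of assembly bColLiv1.pat.W.v2. Only the chromosome and the length of the gene span were taken from that table, and no coordinates are given because the submitters' build is not known. The gene span includes introns. The totals of 17953704 to 23344086 counts per library set the precision of low genes.

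Groups come from the treatment label of the sample record that each table is attached to. The library number in 9 of 10 table names differs from the number in the sample title, and a second link by title was run as an alternative. Genes were kept by filterByExpr with a minimum count of 10, which left 14172, and scaled by TMM. Race was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. The biological coefficient of variation was 0.377.

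A total of 32 gene lists of pathways, complexes and cell types, with 1121 distinct symbols, was written before the data were examined, as were the tests, the rule for naming genes and most of the other settings tried. The 31 lists with at least 5 measured members were tested by camera with a preset correlation of 0.01, and again with an estimated correlation and by fry. Each list also has a level per library, the mean log2 CPM of its members with a prior count of 2 minus the control mean, compared by an exact permutation test over all assignments of 5 birds to each group. Genes named are those that passed, to 10 per direction, with an average log2 CPM of at least 1 and no overlap between groups. Where fewer than 5 passed in a direction, those of smallest p made up the number, and in each list the 3 members of smallest p were named, except for some that are not reported here. RPS26, RPLP0, RPS29 and RPS6 among ribosomal proteins, the forebrain genes and the genes of the closing observations were chosen after their values were seen.

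Alternatives were RLE and plain library size scaling, other filters, limma voom, DESeq2 1.42.0, a surrogate variable from sva 3.50.0, leaving out each library in turn, other thresholds, list levels with other prior counts and as medians, and all genes for the principal components. After seeing the data, fits without chosen libraries, with a term for W-linked expression, with offsets for gene span, and without Z and W genes were added. The pipeline was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, which gave 1 false call among 99 calls. A simulated lowering of the cytosolic ribosomal list by a log2 of 0.4 was recovered with a median of -0.34, and with no effect 0 lists were called. The simulated genes varied independently, while the estimated correlation within that list was 0.377 in the data. The simulation therefore cannot show how often camera at its preset correlation calls a list by chance in these data.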

Results

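Gene expression was measured by RNA sequencing in the cerebellum of racing homers, domestic pigeons bred and trained to return to their loft. The race group held 5 birds killed after returning from a 300 km competition flight, and the control group held 5 birds of like age that stayed in the loft that day. By the labels each library came from a separate bird, and the p-values below take the spread between libraries as that between birds. The deposited counts covered 22547 genes and summed to between 17953704 and 23344086 per library, with 16730 to 17613 genes detected. No pair of libraries agreed within sampling noise, with a lowest chi-square of 27.7 per gene over 45 pairs. The labels disagree on which table belongs to which bird. For 9 of the 10 samples the library number in the table's name differs from that in the sample's title, and following the titles would move 6 tables to the other group. Groups here follow the sample record to which each table is attached, and every direction below rests on that link.

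The control and race libraries also differed in their expression of genes on the W chromosome, which in birds is carried by females. Of 195 W-linked protein-coding genes in the annotation of assembly bColLiv1.pat.W.v2, 94, 95 and 93 reached 1 CPM in control 3, control 4 and control 5. In the other 7 libraries, which include every race library, 24 to 33 did. Below, only libraries with the higher number are said to express W-linked genes. Why 24 to 33 reached 1 CPM in the others was not tested. Control 4 stood apart further. In that library TBR1 and LHX6, transcription factor genes of the forebrain, stood at 77.5 and 34.6 CPM, and their highest values in the other 9 libraries were 2.59 and 1.62 CPM. Control 1 differed from all others in its gene profile, with a median Spearman correlation of 0.879 to the other libraries and a TMM factor of 0.794.

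**Figure D1:**
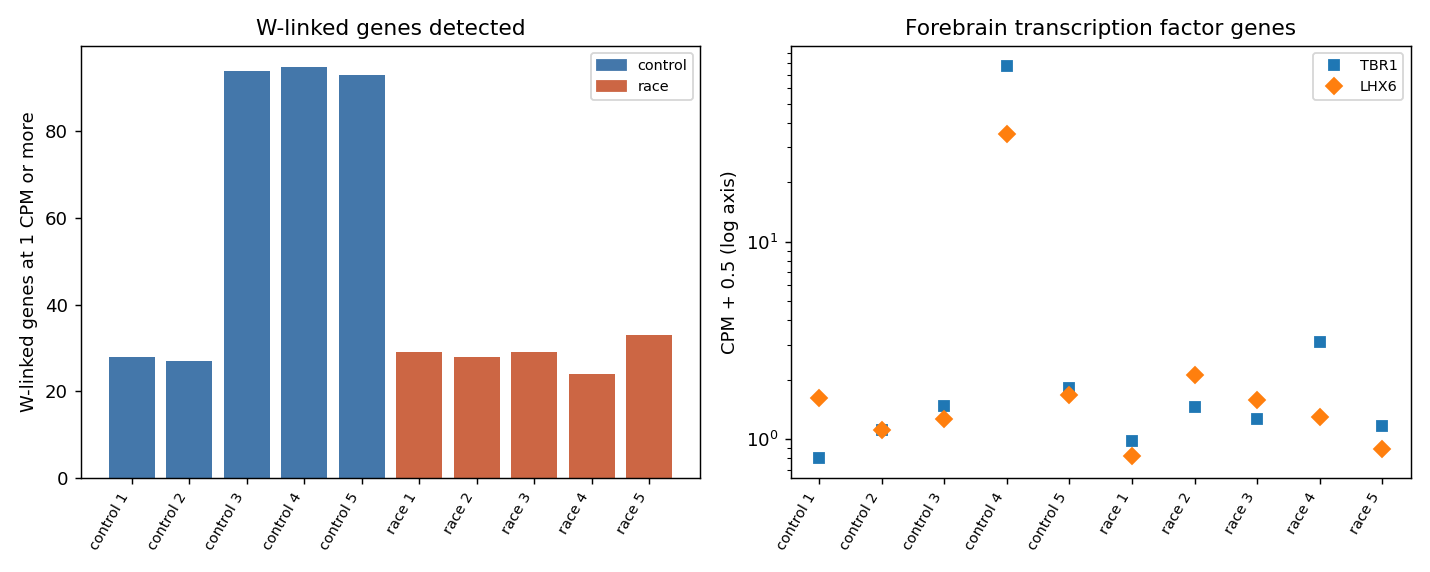
Number of W-linked genes at 1 CPM or more in each library (left, bars coloured by group) and CPM plus 0.5 of the forebrain transcription factor genes TBR1 and LHX6 in each library (right, log axis). Control 3, control 4 and control 5 hold 93 to 95 detected W-linked genes against 24 to 33 elsewhere, and control 4 alone has TBR1 at 77.5 CPM.

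The first comparison asked which single genes differed between the cerebellum of birds that had flown and of birds that had rested. No gene passed. The genes of smallest p that stood higher in race birds were SLC35D2, a nucleotide sugar transporter, VLDLR, a receptor for reelin and lipoproteins, TENT2, a poly(A) polymerase, CAPN2, a calcium-activated protease, and TSTD2. SLC35D2 averaged 10.8 ± 4.14 CPM in control and 34.0 ± 4.76 CPM in race libraries (mean ± SD, n = 5 each), a log2 fold change of 1.65 ± 0.24 (SE). VLDLR averaged 41.6 ± 9.53 and 88.4 ± 13.01 CPM, a log2 fold change of 1.09 ± 0.18. For TENT2, CAPN2 and TSTD2 the log2 fold changes were 0.97 ± 0.17, 0.95 ± 0.17 and 0.88 ± 0.17. SLC35D2, VLDLR, TENT2 and TSTD2 all lie on the Z chromosome.

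On the lower side stood TPPP3, a tubulin polymerization promoting protein, SFRP5, a secreted Wnt antagonist, MLPH, which links melanosomes to myosin, PCP4, a calmodulin regulator abundant in Purkinje cells, and DMAC2, an assembly factor of respiratory complexes. TPPP3 averaged 25.4 ± 5.15 CPM in control and 9.99 ± 2.97 CPM in race libraries, a log2 fold change of -1.35 ± 0.24. PCP4 averaged 70.7 ± 29.7 and 27.2 ± 4.22 CPM, a log2 fold change of -1.38 ± 0.27. The log2 fold changes of MLPH, SFRP5 and DMAC2 were -2.49 ± 0.48, -1.83 ± 0.35 and -1.0 ± 0.21. In all 10 of these genes every race library lay on the same side of every control library. Their choice by smallest p in these same libraries favours that, so it is no separate support. Such a separation was found in 613 of 14172 genes tested, or 4.33%, where chance gives 0.794%.

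By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 14172 genes passed a threshold of 0.05, and the lowest adjusted p was 0.267. At an unadjusted p under 0.05 there were 1889 genes, 877 higher and 1012 lower in race libraries, where 709 would be reached by chance. Limma voom called 0 genes, and DESeq2 called 260, of which 162 were higher, 98 lower and 84 on the Z chromosome. In simulated libraries of this design the same test recovered 22% of genes changed 2-fold and 76% of genes changed 4-fold.

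**Figure D2:**
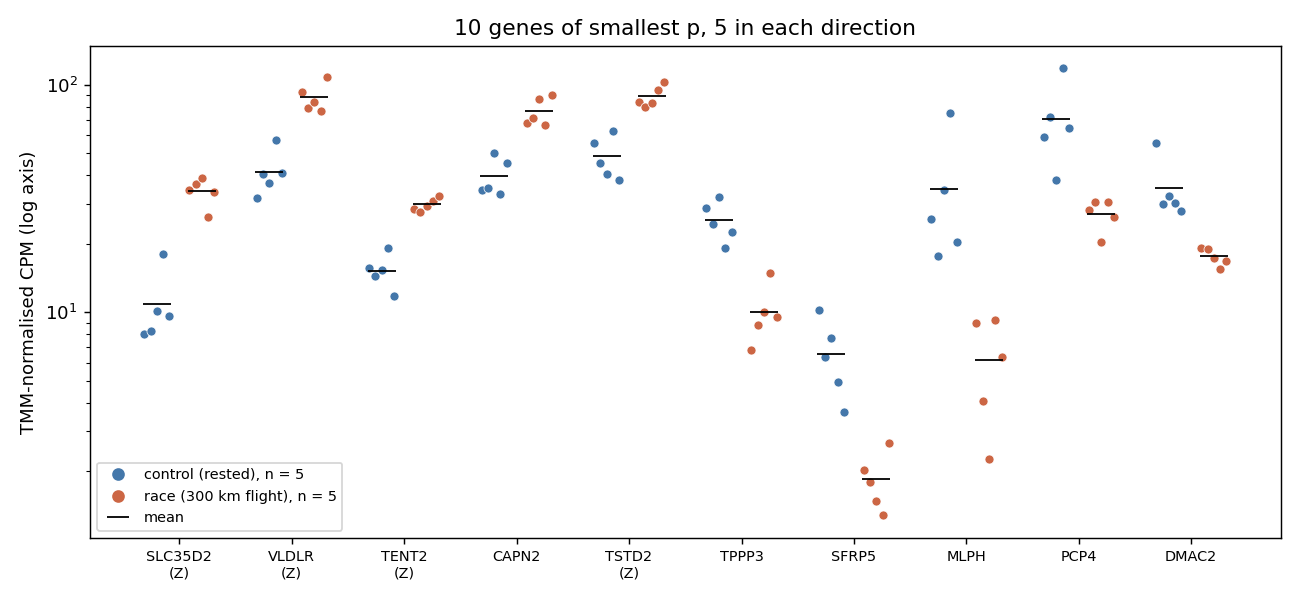
TMM-normalised CPM on a log axis of the 5 genes of smallest p in each direction, 1 point per bird, with the group means as bars and genes of the Z chromosome marked. The groups do not overlap in any of the 10 genes, and none passed the adjusted threshold.

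The series title names the ribosome, and the next comparison asked whether genes of the translation apparatus moved together. Cytosolic ribosomal protein genes were lower in race birds as a group. Of 66 measured members 65 had a negative log2 fold change, with a median of -0.39, or -23.6%, and 35 were lower at an unadjusted p under 0.05. RPS26, RPLP0 and RPS29 had the most negative values, -0.81, -0.73 and -0.68, and the members of smallest p were RPL38 at -0.52 ± 0.13, RPL37A at -0.43 ± 0.13 and RPS27A at -0.59 ± 0.18. RPS6, a Z-linked gene, was the exception at 0.23 ± 0.19. RPL38 averaged 124 ± 7.87 CPM in control and 86.9 ± 7.10 CPM in race libraries.

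The list of cytosolic ribosomal proteins passed camera with its preset correlation of 0.01 (adjusted p = 3.02e-16) and not when the correlation was estimated (adjusted p = 0.288 with an estimated correlation). No member passed over all genes or adjusted over the list alone. All 5 race libraries lay below the control mean, with a list level lower by a mean log2 of -0.35, and an exact two-sided permutation test over all assignments of the birds gave p = 0.0238, or 0.141 after adjustment over the lists. The list's level was highest in control 1, at 0.27, and lowest among controls in control 4, at -0.28. Control 4 thus lay within the race values of -0.50 to -0.17. With offsets for gene span the median was -0.24 (camera adjusted p = 5.26e-06), and with these and without control 3, control 4 and control 5 it was -0.20 and the call was lost (0.136). Reads outside annotated features made up 15.1% to 20.0% in control and 19.4% to 20.8% in race libraries. With groups taken from the sample titles, the median was -0.07 and the list did not pass camera (adjusted p = 0.458).

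**Figure D3:**
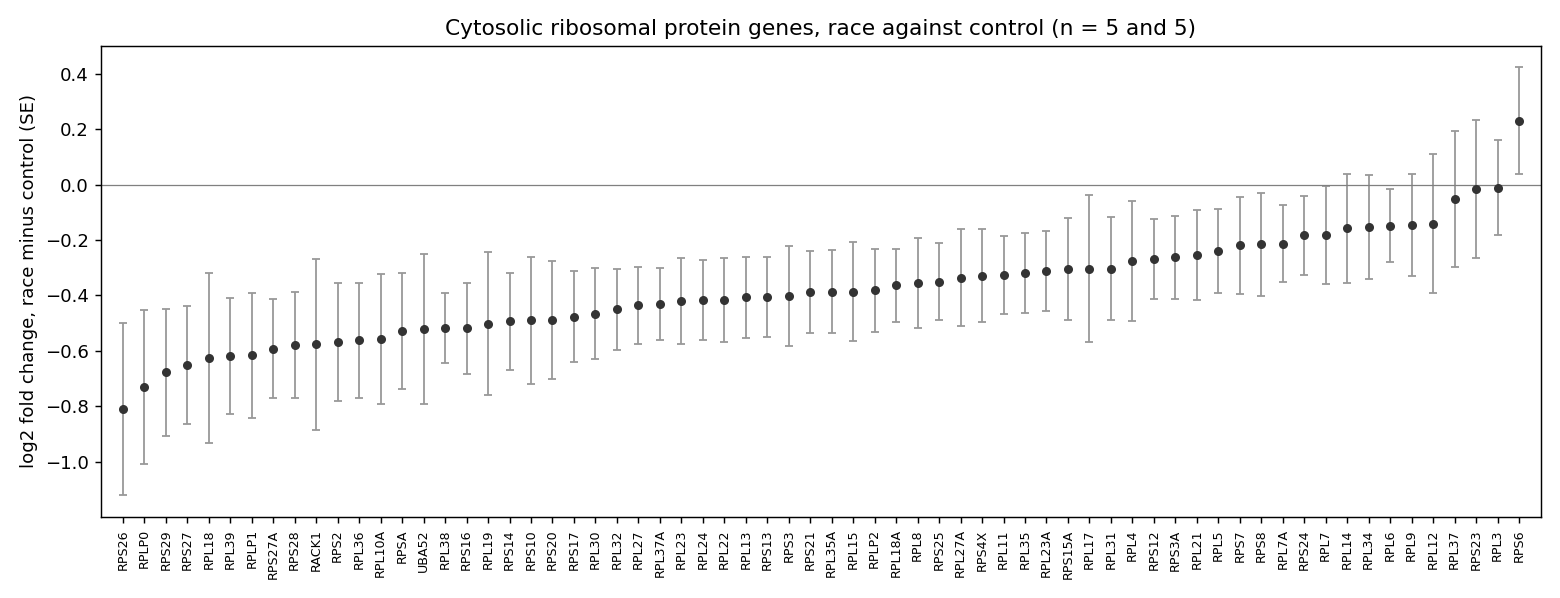
Log2 fold change, race minus control, of the 66 measured cytosolic ribosomal protein genes, ordered by value, with standard errors from the edgeR fit as bars. Values run from -0.81 for RPS26 to 0.23 for RPS6, with 65 of 66 below 0.

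Mitochondrial ribosomal proteins were also lower in race birds by camera (adjusted p = 2.34e-07; adjusted p = 0.288 with an estimated correlation). Of 69 members 61 had a negative log2 fold change, with a median of -0.26, and MRPL20, MRPS11 and MRPS15 stood at -0.53, -0.50 and -0.40. With gene span offsets that median was -0.16, and with these and without control 3, control 4 and control 5 the call was lost at -0.20 (camera adjusted p = 0.160). Translation initiation and elongation factors passed with a smaller median of -0.18 and 35 of 42 members negative (camera adjusted p = 0.0156; adjusted p = 0.288 with an estimated correlation). That call was lost without control 2 (adjusted p = 0.0648), without control 5 (0.0652), with a W term (0.0702) and by plain library size scaling (0.0596). Their members of smallest p were EIF1, which selects the start codon, at -0.61 (-0.36 without control 1), EIF5A2 at -0.36 and EIF3F at -0.27. Genes of ribosome biogenesis did not pass, with a median of -0.11 over 55 members (camera adjusted p = 0.563), or -0.06 without control 1. Its members of smallest p, UTP15, RIOK2 and BRIX1, were all higher in race birds, at 0.65, 0.98 and 0.64, and all lie on the Z chromosome. No member of these 3 lists passed over all genes or adjusted over the list alone.

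A further question was whether energy metabolism and protein maintenance differed after the flight. Nuclear genes for oxidative phosphorylation subunits were lower in race birds, with 47 of 50 members negative and a median log2 fold change of -0.41 (camera adjusted p = 9.28e-13; adjusted p = 0.288 with an estimated correlation). ATP5MG, a subunit of ATP synthase, stood at -0.87 ± 0.23, and the complex I genes NDUFB8 and NDUFB3 at -0.58 and -0.50. The median was -0.23 with gene span offsets and -0.25 without control 1 and control 2. The 13 protein-coding genes of the mitochondrial genome were looked for under their usual symbols, and 0 were found among the gene names. Glycolysis genes did not pass (median -0.25, camera adjusted p = 0.126), with TPI1, PGAM1 and GAPDH at -0.37, -0.54 and -0.46. Genes of the tricarboxylic acid cycle and fatty acid oxidation had a median of -0.13 (camera adjusted p = 0.155), with ETFB, IDH2 and HADH at -0.94, -0.72 and -0.34. Part of these values rests on control 1, without which the glycolysis median was -0.10 and PGAM1, GAPDH, ETFB and IDH2 stood at -0.22, -0.23, -0.52 and -0.30.

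Heat shock proteins and co-chaperones were lower in race birds, with 27 of 31 members negative and a median of -0.42 (camera adjusted p = 1.34e-06; adjusted p = 0.288 with an estimated correlation). Without control 3, control 4 and control 5, which express W-linked genes, the median was -0.06 and the call was lost (camera adjusted p = 0.226). A W term, which makes the same comparison, also gave -0.06 (camera adjusted p = 0.273). BAG3, a co-chaperone of HSP70 in selective autophagy, averaged 101 ± 56.2 CPM in control and 33.4 ± 4.72 CPM in race libraries, a log2 fold change of -1.60 ± 0.34. HSPA2 and DNAJB1 stood at -1.27 and -1.47, and DNAJB1 reached 81.4 CPM in control 1 against 16.6 to 25.2 CPM in the other controls, and stood at -0.82 without it. Genes of autophagy and the proteasome had a median of -0.22 with 45 of 51 negative (camera adjusted p = 0.000122; adjusted p = 0.288 with an estimated correlation). PSMB7, PSMB5 and PSMA1, all core proteasome subunits, stood at -0.55, -0.73 and -0.34, and PSMB5 at -0.33 without control 1.

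Antioxidant genes were lower with 25 of 31 negative and a median of -0.38 (camera adjusted p = 0.000322; adjusted p = 0.288 with an estimated correlation). Without control 1 the median was -0.23, and without control 1 and control 2 it was -0.15 and the call was lost (camera adjusted p = 0.0690), as it was with gene span offsets and without control 3, control 4 and control 5 (0.153). MGST3 and MGST1, microsomal glutathione transferases, stood at -1.0 and -0.56, and the peroxiredoxin PRDX1 at -0.43. Over all genes, 0 members of the heat shock, proteasome and antioxidant lists passed. The counts adjusted over the list alone were 1 for heat shock, 0 for autophagy and the proteasome and 1 for antioxidants. Heat shock genes had a median of 0.29 with groups taken from the sample titles (camera adjusted p = 0.000479), the opposite direction.

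**Figure D4:**
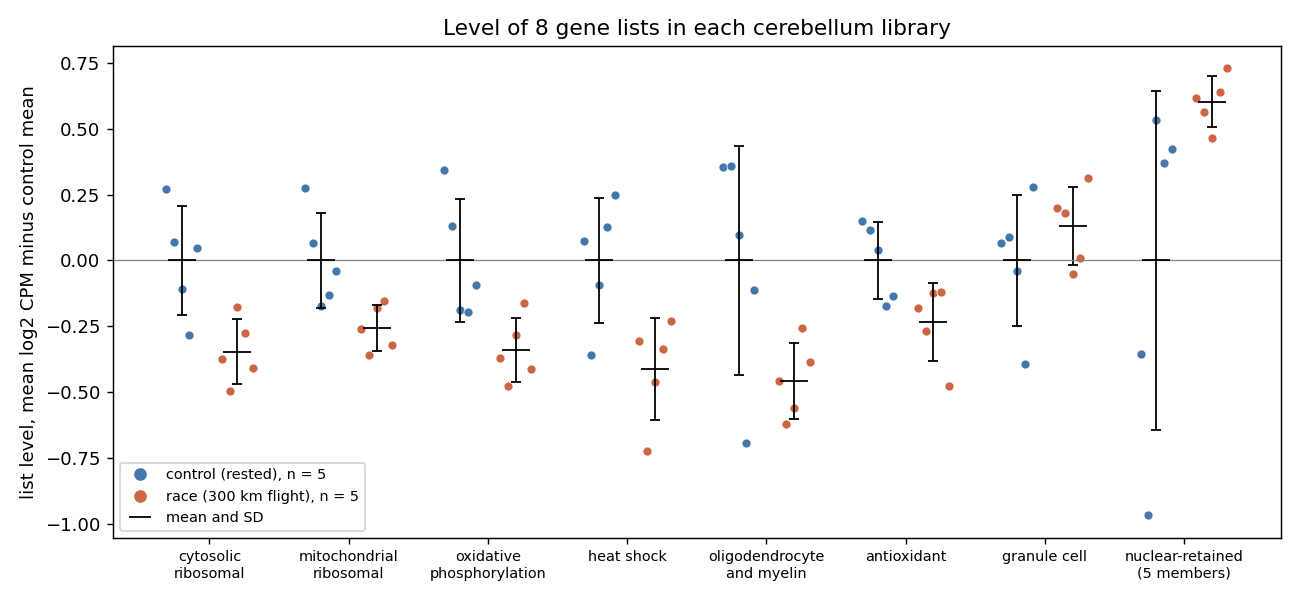
Level of 8 gene lists in each library, as mean log2 CPM over members minus the control mean, 1 point per bird, with group means and SD. The 5 race libraries lie below the control mean for cytosolic ribosomal proteins, at a mean of -0.35, and above it for the 5 measured members of the nuclear-retained list, none a histone, at 0.60.

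Genes that respond to neuronal activity, stress hormones and oxygen were compared next. Immediate early genes were lower in race birds, with 20 of 32 negative and a median of -0.26 (camera adjusted p = 0.0372; adjusted p = 0.532 with an estimated correlation). That call was lost with limma voom (adjusted p = 0.0752) and without any single one of control 1, control 4, control 5, race 1, race 2 or race 5 (0.0668 to 0.165), as well as without control 3, control 4 and control 5 (0.199) and with gene span offsets (0.168), and without control 1 the median was -0.17. NR4A2, an orphan nuclear receptor, stood at -1.68 ± 0.43, the AP-1 gene FOSL2 at -1.26 and DUSP6, a phosphatase of ERK, at -0.98. Glucocorticoid-responsive genes did not pass as a list (median 0.04, camera adjusted p = 0.574), and the median was -0.03 without race 3 and -0.05 without race 4. Among them FKBP5, a co-chaperone of the glucocorticoid receptor, had a log2 fold change of 1.56 ± 0.52 with 83.4 ± 36.2 CPM in control and 246 ± 166 CPM in race libraries. PLIN2, which coats lipid droplets, and KLF9 stood at 0.68 and 0.68 and lie on the Z chromosome. Of these 2 lists, the glucocorticoid list had 1 member and the immediate early list 0 adjusted over the list alone.

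Endoplasmic reticulum stress genes did not pass (median -0.23, or -0.12 without control 1, camera adjusted p = 0.156). ERN1, a sensor of unfolded proteins, stood at 0.57 and passed with VLDLR when adjusted over the list alone, and MANF, at -0.63, did not. Circadian clock genes had a median of 0.06 (camera adjusted p = 0.521), with DBP, BHLHE40 and NR1D2 at -0.96, -1.15 and 0.34. Hypoxia-inducible genes had a median of -0.03 (camera adjusted p = 0.886), with ANKRD37 at 0.64, VEGFA at 0.42 and the glucose transporter SLC2A1 at -0.65. Interferon-stimulated genes had a median of 0.24 (camera adjusted p = 0.155), with IFIH1, HELZ2 and PARP9 at 0.84, 0.36 and 0.81, and passed without race 5 at 0.25 (adjusted p = 0.0173). Inflammatory genes had a median of -0.07 and a camera direction of up (adjusted p = 0.986), with IL1R1 at 1.60, VCAM1 at -1.21 and NFKB1 at 0.60. Cryptochrome and iron genes had a median of 0.05 (camera adjusted p = 0.361), with ISCA2 at -0.39 and the ferritin gene FTH1 at -0.49. Without control 1 MANF, DBP, SLC2A1 and NFKB1 stood at -0.41, -0.55, -0.34 and 0.39, and without control 4 BHLHE40 stood at -0.29. With 1 library left out the medians ran from 0.04 to 0.14 for clock genes, -0.11 to 0.00 for hypoxia, 0.09 to 0.30 for interferon, -0.25 to 0.10 for inflammation and 0.04 to 0.12 for cryptochromes and iron.

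Markers of cell types were compared to see whether the makeup of the samples differed. Oligodendrocyte and myelin genes were lower in race birds, with 17 of 19 negative and a median of -0.49 (camera adjusted p = 4.65e-05; adjusted p = 0.328 with an estimated correlation). CNP and MAG, proteins of the myelin sheath, stood at -1.13 ± 0.29 and -1.38 ± 0.41, and ERMN at -0.83. Adjusted over the list alone 3 members passed, against 0 over all genes. The list level was at 0.35 in control 1, 0.36 in control 2 and -0.69 in control 4, so the controls spanned the race values of -0.62 to -0.26. Without control 1 the median was -0.32, and without control 1 and control 2 it was -0.28 and the call was lost (camera adjusted p = 0.192), while without control 3, control 4 and control 5 it was -0.91. Astrocyte and Bergmann glia genes were lower with a median of -0.28 and 12 of 16 negative (camera adjusted p = 0.0299; adjusted p = 0.288 with an estimated correlation). That call was lost without any single one of control 2, control 3, race 2, race 3 or race 4 (adjusted p from 0.0535 to 0.0901). With 1 library left out the median ran from -0.44 to -0.17, and without control 3, control 4 and control 5 together the median was -0.15 (camera adjusted p = 0.116). GFAP, the main intermediate filament of astrocytes, stood at -1.34 ± 0.44, HEPACAM at -0.99, or -0.44 without control 1, and S100B at -0.70.

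Neuronal marker lists did not pass in the chosen fit. Granule cell genes had a median of 0.10 (camera adjusted p = 0.273), with PAX6, ETV1 and the receptor subunit GABRA6 at 0.37, 0.38 and 0.51. Purkinje cell genes had a median of -0.10 (camera adjusted p = 0.361), with PCP4 the 1 member that passed when adjusted over the list alone, ATP2A3 at -2.12 and GAD1 at 0.44. Inhibitory interneuron genes had a median of 0.08 (camera adjusted p = 0.361), with PRKCD at -1.51, NXPH1 at 0.34 and GAD2 at 0.45. Glutamate and GABA receptor genes had a median of 0.07 (camera adjusted p = 0.886), with GABRA5, GABRA3 and GRM3 at -3.52, -0.99 and -0.75. GABRA5 stood at 33.2 CPM in control 4 and at most 1.57 CPM in every other library. Genes of adjoining brain regions had a median of -0.27 (camera adjusted p = 0.361), with TBR1 at -3.88 and HOXB7 at -0.62. ATP2A3 reached 192 CPM in control 4 against 8.86 to 29.7 CPM in the other controls, and without control 4 ATP2A3, PRKCD, GABRA5, GABRA3, GRM3 and TBR1 stood at -0.41, -0.02, -0.80, -0.57, -0.38 and 0.39. ETV1, GABRA6, GAD1, NXPH1 and GAD2 stood at 0.23, 0.29, 0.28, 0.22 and 0.29 without control 1, GAD1 at 0.29 without race 4 and HOXB7 at -1.22 without race 1. Purkinje cell genes passed at -0.42 with gene span offsets and without control 3, control 4 and control 5 (camera adjusted p = 0.0207), and genes of adjoining regions at -0.76 without a count filter (0.0437). The medians with 1 library left out ran from 0.07 to 0.19 for granule cells, -0.27 to 0.00 for Purkinje cells, 0.01 to 0.24 for interneurons, -0.03 to 0.11 for receptors and -0.46 to -0.09 for adjoining regions.

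Vascular and blood markers did not pass either. Endothelial and pericyte genes had a median of 0.14 (camera adjusted p = 0.226), with PECAM1, KCNJ8 and ABCC9 at 1.18, 1.32 and 0.98, and passed without race 5 at a median of 0.26 (adjusted p = 0.00297). Microglia and macrophage genes had a median of -0.24 (camera adjusted p = 0.886), with MPEG1 at -1.32 and CSF3R at -1.08. Meningeal and choroid plexus genes had a median of -0.02 (camera adjusted p = 0.956), with COL3A1 at 0.85, AQP1 at -2.30 and KL at -2.25. Erythrocyte genes had a median of -0.09 (camera adjusted p = 0.516), with SLC4A1, ANK1 and HEMGN at -1.26, -0.43 and -0.46. Blood leukocyte genes had a median of -0.09 over 6 members (camera adjusted p = 0.653), with JCHAIN at 1.12, ITGA2B at -1.05 and THBS1 at -0.51. AQP1 and KL stood at 121 and 16.1 CPM in control 4, against 3.08 to 15.3 and 0.594 to 2.95 CPM in the other controls, and at -0.49 and -0.70 on the log2 scale without it. MPEG1, CSF3R, ANK1 and ITGA2B stood at -0.46, -0.34, 0.06 and -0.58 without control 1, KCNJ8 and JCHAIN at 0.77 and 0.63 without race 4, THBS1 at -0.32 without control 2, and HEMGN ran from -0.70 to -0.23 with 1 library left out. The medians ran likewise from 0.04 to 0.26 for endothelial genes, -0.42 to 0.12 for microglia, -0.26 to 0.14 for meninges, -0.28 to 0.02 for erythrocytes and -0.24 to 0.00 for leukocytes.

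A list drawn up for nuclear-retained and histone transcripts was the only one of 31 that passed with higher values in race birds, on 5 of its 18 members. These were SRSF5, OGT, LUC7L3, CLK4 and CLK1, protein-coding genes without a histone among them, so nothing is said here of histone or non-coding transcripts. All 5 were higher, with a median of 0.46 (camera adjusted p = 0.00678; adjusted p = 0.452 with an estimated correlation). SRSF5, a splicing factor, stood at 0.83 ± 0.28, the glycosyltransferase OGT at 0.63 and LUC7L3 at 0.45 (0.29 without control 1 and 0.30 without control 2), and 0 passed over all genes or adjusted over the list alone. The list level was -0.35 in control 1 and -0.97 in control 2, and 0.37 to 0.53 in the other controls against 0.46 to 0.73 in race libraries. Without control 2 the median was 0.30 and the call was lost (camera adjusted p = 0.05002), without control 1 and control 2 it was 0.07 (0.274), and without the other 3 controls it was 1.42. In all, 11 of 31 lists passed camera, 10 lower and 1 higher. With an estimated correlation 0 passed, with a lowest adjusted p of 0.288, and 3 lists had an unadjusted p under 0.05. By exact permutation of list levels 8 lists had p under 0.05 and 0 passed after adjustment, where the smallest p possible is 0.00794.

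Genes of the Z chromosome, of which male birds carry an extra copy, stood higher in race libraries. Of 682 Z-linked genes tested 570, or 83.6%, had a positive log2 fold change, with a median of 0.45 and an interquartile range of 0.15 to 0.70. The median over genes of other chromosomes was -0.05. With groups taken from the sample titles the Z median was -0.10 against 0.008 for other genes, the opposite direction. Z-linked genes made up 28.4% of the genes higher at an unadjusted p under 0.05 and 4.81% of the genes tested (249 of 877; Fisher's exact test, odds ratio 11.8, p = 1.51e-133, across genes, which are not independent replicates). The level of Z-linked genes relative to autosomal genes ran from 0.18 to 0.29 on the log2 scale in race libraries. In controls 1 to 5 it was -0.41, 0.03, -0.37, 0.04 and -0.48.

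Principal components of the 1000 most variable genes were used to see how the libraries fell. The first component took 26.3% of the variance and did not separate the groups (exact permutation p = 0.984). It set control 4, at 49.9, against control 1, at -35.0. The second took 19.5% and separated all race from all control libraries, with means of -14.7 and 14.7 (exact two-sided permutation p = 0.00794, the smallest possible, and 0.0238 after Benjamini-Hochberg adjustment over 3 components). The control mean rests mostly on control 1, control 2 and control 4, at 27.6, 17.5 and 29.2. Control 3 and control 5, at -1.86 and 0.87, lay closest to the race libraries, which ran from -22.8 to -6.94. Genes with the largest positive weights stood highest in control 4, such as CAMKV at 483 CPM against at most 7.83 CPM in the other controls. Whether the component reflects the flight or these libraries was not tested.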

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

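The tests of gene span, left-out libraries, W-linked genes, forebrain genes and Z-linked genes were chosen after the results were seen, with their bounds. The counts over other splits of the birds followed a rule set before the splits were run. For each measure, list level and named gene, the farthest library of each group was compared with its nearest neighbour, as that gap divided by the group's range, with a bound of 0.71 for 5 birds. Of 288 groups of values 27 exceeded it, where chance alone gives 14.4.

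Control 4 accounted for 8 of the 27. Its mean log2 level of 12 forebrain genes was 3.79 against 0.18 to 0.57 in the other controls (gap ratio 0.892), with TBR1 at 0.789. High values were also found for GABRA5 (0.843), GRM3 (0.751), PRKCD (0.789) and SLC35D2 (0.713), and low ones for ANKRD37 (0.758) and ERMN (0.737). The 12 forebrain genes had a median log2 ratio of 3.18 over the mean of the other 9 libraries, so a candidate explanation is forebrain tissue in this sample. A sample wholly of another region is argued against by the granule cell genes, which were lower by a median log2 of -0.55. Their spread was wide. ZIC2, ZIC1 and ZIC4 fell furthest, at -1.29, -1.25 and -1.06, while SLC17A6, TIAM1 and CALB2 were higher, at 0.60, 0.42 and 0.37. RNA of more than 1 bird may also be present, since 60 W-linked genes stood at a median log2 ratio of -1.34 to control 3 and control 5 (58 of 60 lower). Autosomal genes had a median of -0.04. The 60 were picked for at least 1 CPM in control 3 and control 5 and under 0.1 CPM on average in the 7 others. Picking on control 3 and control 5 favours a lower ratio, by an amount that was not tested, and the autosomal genes were not picked so. No biological explanation was tested for this library.

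The lower cytosolic ribosomal protein genes were weighed against 3 explanations other than the flight, namely control 1 and control 2, gene span and sex. A lean toward genes of chromosomes 20 to 39, given for control 1 further below, was not tested for this list, nor was base composition. Without control 1 and control 2 the median was -0.30 with 61 of 66 members lower, which argues against these libraries as the whole source. In that fit every remaining control expressed W-linked genes and no race library did, so W status and flight coincide in it. With offsets for gene span over all libraries, the list's median went from -0.39 to -0.24 and the list still passed camera (adjusted p = 5.26e-06). A trend may thus account for part, and gene span with introns is an imperfect stand-in for transcript length. That rests on a bound of -0.25 for excluding a length trend, set with the value known, and the bound of -0.2 used for the other 2 explanations would exclude it. Without control 3, 4 and 5 the median was -0.53 (camera adjusted p = 2.79e-09). A W term, which repeats that comparison, also gave -0.53 (4.55e-10). Without control 3, 4 and 5 and with the offsets the median was -0.20 and no longer past camera (0.136). Sex and flight cannot be told apart for this list, because control 1 and control 2 alone remain. An effect of the flight, as the design names it, stays open and was not separated from these.

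The higher Z-linked genes in race libraries were weighed against the sex of the birds. Control 3 and control 5 had low Z and high W expression, as female birds would. Control 1 and control 4 did not pair in that way. Relative to autosomal genes, Z stood at -0.41 in control 1, without W-linked expression, and at 0.04 in control 4, with it. Control 2, also without it, stood at 0.03, so control 1 is the farther from the race libraries of the 2 controls used next. Among the 7 libraries without W-linked expression the medians of Z-linked and other genes were 0.47 and 0.04, against 0.45 and -0.05 over all 10, and with gene span offsets 0.27 and -0.03, against 0.39 and -0.07. With offsets the difference of 0.30 lies between the bounds of 0.1 and 0.4, and without them it lies above 0.4, so sex and flight cannot be told apart for Z-linked genes, because 2 controls remain and control 1 is atypical in gene profile. In those 7 libraries, without offsets, SLC35D2, VLDLR, TENT2, TSTD2, PLIN2 and KLF9 stood at 2.06, 1.29, 1.0, 0.82, 0.73 and 0.54. The first 5 passed edgeR's quasi-likelihood test (adjusted p from 0.00530 to 0.0270), as did 3416 genes in all in that fit, 166 of them on Z. These values kept their direction at equal W status but rest on the same 2 controls, and passing there does not set these genes apart.

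Other splits of the 10 birds into 5 and 5 were fitted, 100 of the 126 possible. For genes past the adjusted threshold of edgeR's quasi-likelihood test, the observed number is 0, which all 100 splits reach by definition, and the highest of the others gave 9, so this count tells nothing about chance. For genes at an unadjusted p under 0.05, 2 of the 100 drawn reached 1889, with 2695 the highest of the others, which sets control 1, control 2, race 2, race 3 and race 4 against the rest. The share of 2 in 100 is under 0.05 over those drawn, with no adjustment for the other measures put to the same splits. Since 26 of the 126 were not fitted, chance is not excluded over all possible splits. Nor is it excluded among the 15 drawn that keep the 3 libraries with W-linked expression together, of which 2 reach 1889. For lists past camera, 21 of 100 splits gave 11 or more, so chance is not excluded for that number. The splits other than the observed one called a median of 7 lists and at most 16. For the cytosolic ribosomal list, 4 of 100 splits gave a camera p as small, at a -log10 of 17.0 against 27.4 in the highest other split. That share is under 0.05 over the 100 drawn, by a small margin. With 26 of the 126 not fitted, chance is not excluded over all of them. The splits that reached the observed value each kept control 1, control 2, control 3 and control 5 together. Of the 15 drawn that keep the W libraries together only the observed one gave a camera p as small, 6.67%. These 15 are too few for a share under 0.05, and not every split that keeps those libraries together was drawn.

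Control 1 was far from the other controls in TMM factor (gap ratio 0.754) and in the share of reads aligned to more than 1 place (0.754). It was high for DMAC2 (0.775), DNAJB1 (0.737), PGAM1 (0.847), IDH2 (0.734) and PSMB5 (0.737), and low for NFKB1 (0.781). Control 2 was high for Purkinje cell genes (0.762) and low for PSMA1 (0.819). Race 5 was low for interferon-stimulated genes (0.732), PARP9 (0.937), Purkinje cell genes (0.896) and endothelial genes (0.775). Race 1 was high for microglia genes (0.755), and race 2 was low for RPS27A (0.848) and PSMA1 (0.823). Race 4 was low in TMM factor (0.873) and high for DBP (0.746).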

How the results depend on the processing

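Fits without chosen libraries, with a W term, with gene span offsets or without Z and W genes were added after the data were seen. The W term is no separate check, since it repeats the comparison of race with control 1 and control 2. The 0 genes called by edgeR's quasi-likelihood test held under RLE and plain library size scaling, both filters, limma voom, both other thresholds, gene span offsets and without Z and W genes. DESeq2 called 260 genes. The fit with a surrogate variable called 52, 31 of them on Z and 2 on W. Grouping by the sample titles called 3, LOC102083923, LOC102095531 and LOC102085610, all lower. The count was 106 without control 1 and 2, 72 of them on W and 19 on Z. Without control 1, 2 and 4 it was 265, 81 of them on W and 147 on Z. Every control left in those fits expressed W-linked genes and no race library did, so W status and flight coincide in them. The count was 3416 without control 3, 4 and 5, 2768 with gene span offsets added to that, and 4338 with a W term. Leaving out 1 library gave 0 to 1 gene, with SLC35D2 called without control 4. Plain library size scaling turned the genes at an unadjusted p under 0.05 from 877 higher and 1012 lower to 1087 and 597, and the median of all genes moved from -0.03 to 0.07.

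Of the 11 lists past camera, 11 passed with RLE scaling, 10 with library size alone and 10 with limma voom, and leaving out 1 library kept 8 to 10 of them. Of the 11, the number still past was 5 without control 1 and 2, 7 without control 1, 2 and 4, 7 without control 3, 4 and 5, 4 with gene span offsets added to that, where Purkinje cell genes were gained (-0.42, adjusted p = 0.0207), 7 with a W term, 0 with an estimated correlation and 0 by fry, whose mixed test of change in either direction passed 1, cryptochromes and iron (adjusted p = 0.0324). Library size alone moved the medians of mitochondrial ribosomal, immediate early, antioxidant, autophagy and astrocyte genes to -0.16, -0.16, -0.22, -0.11 and -0.14, still past camera, and a surrogate variable those of antioxidant and oligodendrocyte genes to -0.23 and -0.27. The cytosolic ribosomal median stayed negative throughout. It ran from -0.45 to -0.33 with 1 library left out, was -0.072 by the sample titles (adjusted p = 0.458) and -0.20 without control 3, 4 and 5 and with gene span offsets (0.136), and at -0.39 missed the threshold with an estimated correlation (0.288) and by fry (0.0817). By the sample titles 0 of the 11 lists still passed in the same direction, heat shock genes passed in the opposite one at 0.29 (adjusted p = 0.000479), endothelial and meningeal genes passed at -0.47 (0.000711) and -0.63 (0.000944), translation factors had a median of 0.00083, and 55 of 101 named genes changed sign. Heat shock genes had a median of 0.00014 without control 3, 4 and 5 and with gene span offsets. The cause was not tested for any of these.

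Permutation tests of list levels passed 0 lists under every prior count and as medians. Without control 1 and 2 they passed 0 too, but the 56 assignments of 3 and 5 birds leave little room to pass, and the lists at an unadjusted p under 0.05 went from 8 to 1. The second principal component kept its p of 0.00794 with all genes. The planned sex term was not run because W-linked expression was found in controls only, so both groups did not hold both kinds. No paired analysis was possible because the labels give no number that links a race bird to a control bird. Depth did not separate the groups, and genes under the count filter, 8375 in number, were not tested.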

Other observations

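The genes below were chosen after their values were seen, from those with the largest weights on the second principal component and from per-bird values. ACTN2, a cross-linker of actin filaments, averaged 10.0 ± 7.91 CPM in control and 40.4 ± 22.8 CPM in race libraries (mean ± SD, n = 5 each), a log2 fold change of 2.01 ± 0.55 (SE) that did not pass edgeR's quasi-likelihood test (adjusted p = 0.272). STYXL2 and CCDC141 stood at 2.43 ± 0.90 and 1.46 ± 0.63, and STYXL2, at 20.4 CPM in race 4 and at most 5.57 CPM in the other race libraries, stood at 1.24 without race 4. On the other side stood PDYN and TAC1, neuropeptide precursors, at -3.54 ± 0.88 and -4.12 ± 1.11, BCL11B, a transcription factor of forebrain neurons, at -4.51 ± 1.43, and the immediate early gene EGR3 at -3.54 ± 1.22. Those 4 values rest largely on control 4, where PDYN, TAC1, BCL11B and EGR3 stood at 11.9, 24.6, 55.7 and 93.7 CPM, against at most 1.89, 1.52, 0.939 and 3.40 CPM in the other controls. Without that library their log2 fold changes were -2.02, -1.78, -0.54 and -0.48.

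FKBP5 differed widely between race birds. It stood at 272, 354 and 450 CPM in race 2, race 3 and race 4, and at 90.8 and 64.5 CPM in race 1 and race 5. Controls ran from 36.6 to 118 CPM. The level of glucocorticoid-responsive genes was 0.40 in race 3 and 0.42 in race 4, and -0.05 in race 2, -0.22 in race 1 and -0.25 in race 5.

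Control 1 differed from the others in the kind of genes it held. Genes of chromosomes 20 to 39 stood 1.38 higher on the log2 scale relative to those of chromosomes 1 to 5 than the average library, against 0.23 in control 2 and -0.30 to 0.01 elsewhere. The rank correlation of its deviations with gene span was -0.43, against -0.17 in control 2 and 0.05 to 0.27 elsewhere. Ribosomal RNA genes held 1.06% of its gene counts.

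Both links between tables and birds put the 3 libraries with W-linked expression in a single group. By the sample record they are all controls, and by the library numbers in the titles they are all race libraries.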
